A study of Arabidopsis thaliana with 28 samples.

How the data were processed

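Root tips of Arabidopsis thaliana, accession Columbia-0, were profiled on Affymetrix ATH1 arrays. Per the labels' protocols, seedlings were moved to medium with 1 mM hydrogen peroxide (H2O2) or to control medium, and root tips were cut by hand into the meristematic zone and the elongation zone. Each biological replicate held 30 roots, RNA was extracted with a commercial kit, and labelled cRNA was made with 2 rounds of amplification. The 28 arrays form 14 groups of 2 biological replicates. Control roots were taken at 0, 1, 3 and 6 h and H2O2 roots at 1, 3 and 6 h, in both zones. The number of arrays per group limits the precision of every value, and the p-values rest on the spread between 2 biological replicates per group.

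The deposited values are linear array intensities, 1 signal per probe set and array. The submitters' processing notes name MAS5 and GCRMA without saying which made the values. In the values themselves every array has a mean of 250 once the lowest and highest 2% of probe sets are set aside, which is how MAS5 global scaling leaves an array. The sorted signals differ between arrays, so no quantile normalisation had been applied. Array medians lay between 49.4 and 76.3. Between 24.5% and 31.1% of probe sets per array had a signal under 16. Detection calls were not used here. Values were taken as log2(signal + 16), so a log2 fold change understates the change of dim genes. Signals in the text are linear means ± SD over arrays, and fold changes are given on the log2(signal + 16) scale.

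Of the 22810 probe sets, 64 control probe sets were left out and 22746 were tested. The platform annotation listed 13513 probe sets with 1 gene, 503 with several genes, and did not list 8730. Of the first kind, 13436 were matched by gene ID to a locus in a RefSeq gene table of assembly TAIR10.1, which was used for names alone. These gave 13355 single genes, of which 147 had several probe sets, and the brightest probe set over all arrays then stood for the gene. A probe set with no single gene was counted but not named. MYB30, LTPG1, LTPG2 and LTP5, which the study is known for, were not analysed here, because no probe set was paired with them in that annotation. Probe sets can bind transcripts of close relatives, so values of members of large families such as glutathione transferases, glucosyltransferases and peroxidases carry that uncertainty.

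All arrays entered 1 linear model with a mean per group in limma 3.58.1 (R 4.3.3), with 14 residual degrees of freedom and 5.6 prior degrees of freedom. Contrasts were tested with limma's moderated test (eBayes with an intensity trend), 2-sided, and p-values were adjusted by Benjamini-Hochberg over the 22746 probe sets. A probe set was called at an adjusted p under 0.05. The planned contrasts were H2O2 against control medium at each time in each zone, the difference of these between zones, their change from 1 h to 6 h, the elongation zone against the meristematic zone over the 4 control times, and an F test over time on control medium. These contrasts, the gene lists and the naming rule were fixed before the data were examined. The mean H2O2 effect over 1, 3 and 6 h in each zone, in both zones and as a difference between zones was added after the values were seen, as was the contrast of 1 h against 3 and 6 h among H2O2 arrays.

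Genes were named by rule. For each H2O2 contrast these were up to 6 genes with the highest and up to 6 with the lowest log2 fold change among called probe sets with 1 gene and with both H2O2 arrays on the same side of both control arrays. Up to 4 per direction were taken for zone differences, 3 for changes over time, 8 for the zone comparison and 10 for the added contrasts, plus the 4 smallest p-values per zone for time on control medium. Up to 4 members of each gene list were also named, and other names were chosen after their values were seen. Of 546 entries in 28 fixed gene lists, 117 had a measured gene. The 6 lists with at least 5 measured members were antioxidant enzymes, glutathione transferases and xenobiotic detoxification, heat shock proteins, expansins and xyloglucan hydrolases, class III peroxidases, and auxin response and transport. They were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The 35 measured members of 16 shorter lists were read gene by gene. Families of genes that share the letters of their symbol (193 families) were tested in the same way, chosen after seeing the data.

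The scripts were tested on simulated arrays with known changes in 200 of the 22746 probe sets. For H2O2 in the meristematic zone at 6 h, 46% of changes of 1 on the log2 scale and 97% of changes of 2 were recovered, with 5 and 10 false calls. For the difference between zones at 6 h these shares were 7% and 81.5%. For the mean effect in the elongation zone they were 91.5% and 100%, and for the zone comparison 98% and 100%. Noise was drawn independently for each probe set and array. It held no differences shared by many probe sets, such as those by replicate number among the real arrays. The rates of recovery and of false calls therefore need not hold for the real arrays. Alternatives covered the pseudocount (1 and 64), quantile normalisation, median centring, a filter on dim probe sets, the variance model, the replicate number or root pool as a block, the arrays in the fit, a fold threshold, the 0 h control and each array left out. The closing section gives their effect. Figures were drawn with matplotlib 3.10.9.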

Results

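The series asked which genes respond to H2O2 in dividing and in elongating cells of the Arabidopsis root tip. Signals of 22746 probe sets were read on 28 arrays, 2 for each of 14 groups. The arrays of a group correlated with r between 0.9649 and 0.9867 across probe sets. The first principal component held 75.6% of the variance and separated the meristematic from the elongation zone, and the second component held 4.35%. On the second component 6 of the 8 arrays taken at 1 h lay below the others, while the control arrays numbered 1 of both zones did not. Within every group replicate 1 lay above replicate 2 on that component.

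**Figure D1:**
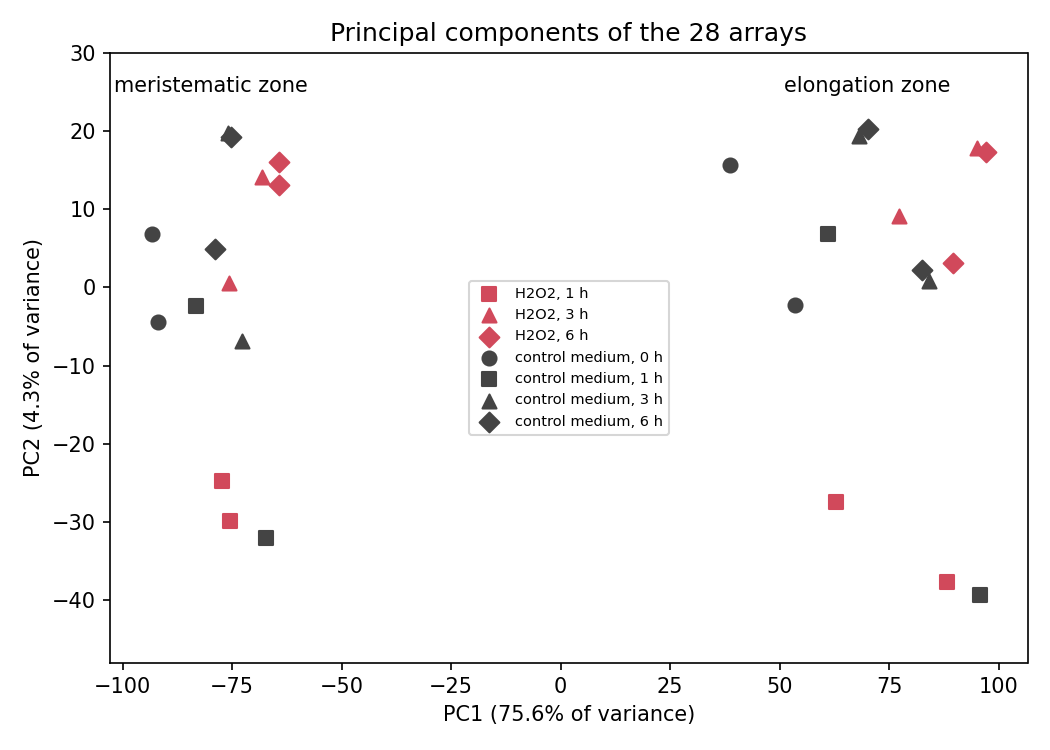
Scores of the 28 arrays on the first 2 principal components (arbitrary units), 1 point per array, with colour for the medium and shape for the time. The zones separate along the first component, and most 1 h arrays lie low on the second.

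The comparison of the zones in control roots asked what distinguished the dissected tissues without H2O2, over the 4 control times. Class III peroxidases and wall-loosening enzymes ranked higher in the elongation zone as lists. The class III peroxidase AT3G01190 had a signal of 7505 ± 1850 (SD, n = 8) in the elongation zone and 42.6 ± 39.4 (n = 8) in the meristematic zone, a log2 fold change of 7.17 ± 0.33 (SE). The peroxidases AT5G17820 (6.19 ± 0.30), AT2G37130 (5.53 ± 0.29) and AT4G11290 (5.29 ± 0.15) followed the same direction. AT1G04040 and AT5G44020, which code for acid phosphatases of the HAD superfamily, were higher by 5.97 ± 0.20 and 5.86 ± 0.21. AT2G30930 (5.81 ± 0.18) and AT4G11210 (5.44 ± 0.16) completed the 8 genes with the highest ratio, all with adjusted p of at most 1.5e-12.

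At the other end, AT1G50060, a member of the family of pathogenesis-related protein 1, was lower in the elongation zone with a log2 fold change of -5.96 ± 0.36. Its signal was 2221 ± 656 (SD, n = 8) in the meristematic zone and 42.8 ± 91.7 (n = 8) in the elongation zone. AT3G19430 (-5.11 ± 0.31), the chitinase family gene AT1G56680 (-4.62 ± 0.15), sks16 (-4.48 ± 0.30) and the pectin lyase-like gene AT1G65570 (-4.48 ± 0.21) were also lower. So were AT3G15240 (-4.46 ± 0.17), AT1G10530 (-4.35 ± 0.22) and ATGSTF13 (-4.32 ± 0.18). The other probe set of AT3G15240 gave -4.04 ± 0.16.

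Of the 34 measured class III peroxidases, 18 were higher in the elongation zone, 1 was lower and the others did not pass, and the same counts held adjusted over the list alone. The list ranked above other genes (camera adjusted p = 1.85e-05, and adjusted p = 0.022 with an estimated correlation). AT4G30170, with signals of 11600 ± 1450 and 749 ± 459 (SD, n = 8 each), and AT2G18980, with 7730 ± 1120 and 398 ± 173, were its brightest named members. Among 13 expansins and xyloglucan hydrolases, which loosen or remodel walls, 9 were higher and 2 lower (camera adjusted p = 0.00546, and adjusted p = 0.0348 with an estimated correlation). XTH21 (4.64 ± 0.12), XTH18 (4.16 ± 0.18) and EXPB1 (3.99 ± 0.11) were higher, whereas EXPA4 was lower (-3.82 ± 0.18). Of 13 glutathione transferases and detoxification genes 7 were higher and 1 lower, led by GSTU28, 12.2-fold higher, and GSTU27 (2.09 ± 0.11), with GSTU25 as the lower one (-0.90 ± 0.16). That list was called by camera (adjusted p = 0.025) but not with an estimated correlation (adjusted p = 0.149).

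Of 7 heat shock genes 5 were lower in the elongation zone and 1 higher, with Fes1A at -1.71 ± 0.12, and camera did not call the list (adjusted p = 0.336). Of 9 auxin genes 2 were higher, among them the homeodomain gene HAT2 (1.33 ± 0.11). Another 4 were lower, among them the auxin repressors IAA20 (-1.68 ± 0.15) and IAA30 (-1.44 ± 0.14). Camera did not call that list (adjusted p = 0.731). Of 5 antioxidant enzymes 1 was higher, the glutathione reductase GR1 (0.49 ± 0.09), and 2 lower, with a camera adjusted p of 0.986 for the list. Fry tests the members without ranking them against other genes. It called the heat shock list (adjusted p = 7.42e-06), the auxin list (adjusted p = 4.98e-05) and the lists named before (adjusted p of at most 2.74e-08). It did not call the antioxidant enzymes (adjusted p = 0.178). Since 58.3% of all probe sets differed between the zones, a fry call does not set a list apart from other genes.

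Of the 35 measured genes of the 16 shorter lists 13 were higher and 11 lower in the elongation zone. The Aurora kinases AUR1 (-2.01 ± 0.09), AUR2 (-2.62 ± 0.16) and AUR3 (-1.88 ± 0.10), which act in mitosis, were lower. The checkpoint gene BUBR1 (-2.68 ± 0.21), the replication genes PRL (-1.70 ± 0.16) and ICU2 (-1.09 ± 0.12) and the stem cell regulator BBM (-3.15 ± 0.10) were lower as well. So were AT3G05060 (-2.90 ± 0.17) and AT5G14520 (-2.77 ± 0.17), of ribosome biogenesis. UPB1, a transcription factor known to balance superoxide and H2O2 at the root transition zone, was higher by 4.66 ± 0.23, with signals of 1143 ± 476 and 27.1 ± 11.6 (SD, n = 8 each). The root hair genes EXPA7 (1.24 ± 0.19) and EXPA18 (0.73 ± 0.12) were also higher.

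In all, 13259 of 22746 probe sets (58.3%) differed between the zones by limma with Benjamini-Hochberg adjustment, 5910 higher and 7349 lower in the elongation zone. With each array shifted to the same median, 16154 were called, 10595 higher and 5559 lower, because the median log2 fold change of all probe sets moved from -0.02 to 0.26. The log2 ratio of 3' to 5' GAPDH control signals, a measure of RNA quality, was 0.0338 ± 0.22 in the elongation zone and 0.432 ± 0.184 in the meristematic zone (SD, n = 8 each; exact permutation p = 0.00617), and it differed along with these gene groups. The same ratio for actin was far larger, 4.04 ± 0.177 in the elongation zone and 4.36 ± 0.389 in the meristematic zone (exact permutation p = 0.0648).

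**Figure D2:**
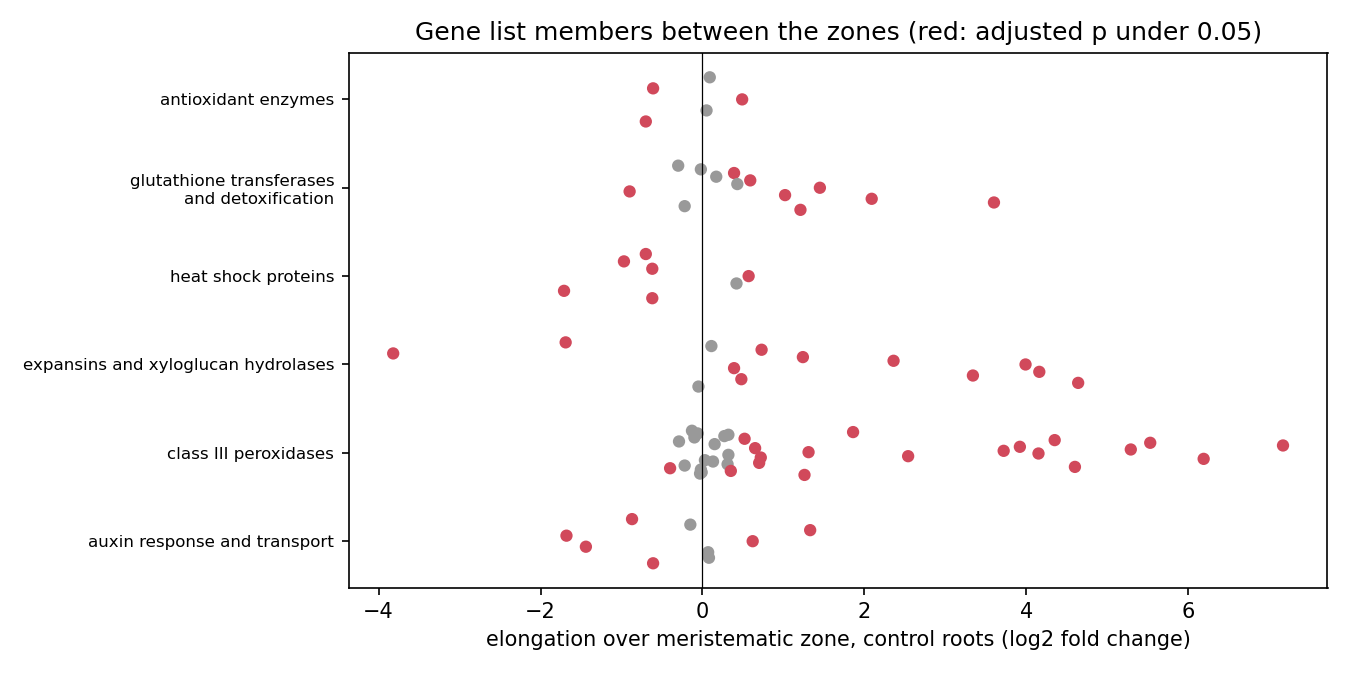
Log2 fold change of elongation over meristematic zone in control roots for each measured member of the 6 gene lists, 1 point per gene, red where the adjusted p was under 0.05. Peroxidases reach 7.17, and EXPA4 lies lowest at -3.82.

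H2O2 was compared with control medium at the same time to find early and later responses of the meristematic zone. The gene with the clearest change was AT2G41810, which codes for a DUF642 cell wall protein. At 3 h its signal was 275 ± 18.4 on H2O2 and 2292 ± 210 on control medium (SD, n = 2 each), 7.91-fold lower (log2 fold change -2.98 ± 0.18, limma adjusted p = 1.43e-08). At 6 h it was still lower (-2.07 ± 0.18, adjusted p = 4.75e-06). AT3G44190, an oxidoreductase of the FAD/NAD(P)-binding family, rose by 1.65 ± 0.23 at 3 h (adjusted p = 0.00673) and 1.79 ± 0.23 at 6 h (adjusted p = 0.00134). AT4G01870, a tolB-related gene, rose by 1.55 ± 0.25 and 1.75 ± 0.25 at these times.

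At 6 h MSRB5, which codes for a methionine sulfoxide reductase that repairs oxidised methionine, rose by 1.60 ± 0.31, from a signal of 217 ± 59.3 to 682 ± 41 (SD, n = 2 each). AT5G61820 (2.03 ± 0.38), the calcium-binding protein gene AT2G46600 (1.36 ± 0.20) and AT2G47890 (1.35 ± 0.25) rose too. The peroxidase AT2G18980 rose by 1.06 ± 0.20 (adjusted p = 0.04). AT5G43450 at 3 h (0.87 ± 0.15) and AT1G67790 at 6 h (-1.15 ± 0.17) also passed, with signals below 24 in both media.

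At 1 h no probe set passed in the meristematic zone by limma. An unadjusted p under 0.05 was found for 511, fewer than the share of 0.05 of 22746 that no effect would give. At 3 h 9 passed, 7 higher and 2 lower, and at 6 h 31 passed, 28 higher and 3 lower. With the replicate number as a block, 6, 37 and 115 passed at 1, 3 and 6 h, so the absence of calls at 1 h rests on the fit without it. Leaving out 1 array gave 2 calls at 1 h (without H2O2 replicate 2), 1 and 5 at 3 h (without control replicate 1 or 2), and 2, 7 and 3 at 6 h (without control replicate 1, H2O2 replicate 1 or H2O2 replicate 2). At 1 h some passed without the control arrays numbered 2 of both zones, as the closing section gives. That fit kept as 1 h controls only those numbered 1, which lay apart from the other 1 h arrays on the second principal component. At 3 h 2 passed with no intensity trend. With only the 4 arrays of a time in the fit, 1 passed at 3 h and 9 at 6 h. MSRB5 and AT5G43450 were not called after quantile normalisation or median centring.

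For elongating cells the same comparison was made at 1, 3 and 6 h. At 3 h BGLU28, a beta-glucosidase, rose 17.3-fold, from a signal of 71.9 ± 10.5 to 1640 ± 958 (SD, n = 2 each; log2 fold change 4.11 ± 0.55, adjusted p = 0.00358). The glucosyltransferase GT72B1 (1.82 ± 0.31), the glutathione transferase GSTU25 (1.69 ± 0.33) and AT4G01870 (1.76 ± 0.25) rose as well. The glutaredoxin GRX480, a redox protein known to bind TGA transcription factors, rose at 1 h by 1.69 ± 0.26 (adjusted p = 0.0183). At that time AT4G01870 (1.68 ± 0.25), the acyltransferase gene AT5G07870 (1.99 ± 0.32) and the methyltransferase gene AT5G10830 (1.09 ± 0.18) had also risen.

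The chitinase family gene AT2G43590 rose at 3 h (1.82 ± 0.33) and 6 h (1.88 ± 0.33), and AT2G41380 rose at 3 h (2.06 ± 0.41). AT2G41810 fell here too, with log2 fold changes of -1.34 ± 0.18 at 3 h and -1.45 ± 0.18 at 6 h. AT5G62340, an inhibitor of invertases or pectin methylesterases by family, fell at 6 h (-1.46 ± 0.22, adjusted p = 0.0119). Calls at signals of at most 50 in both media were AT3G03670 and AT3G63360, lower at 3 h, AT4G37290, AT4G20930 and AT5G61710, higher at 6 h, and AT5G53320, which was lower at 1 h (-1.29 ± 0.18) and higher at 6 h (1.83 ± 0.18).

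By limma with Benjamini-Hochberg adjustment 7 probe sets passed at 1 h (6 higher, 1 lower), 31 at 3 h (27 higher, 4 lower) and 13 at 6 h (11 higher, 2 lower). With the replicate number as a block, 38, 67 and 54 passed at these times. Leaving out 1 array gave 2 and 207 calls at 1 h (without control replicate 1 or 2) and 0 without either H2O2 replicate; at 3 h 7 and 17 (control) or 1 and 12 (H2O2); and at 6 h 5 without control replicate 1 and 2 without H2O2 replicate 2. At 1 h 11 passed with a pseudocount of 64 and 3 with no intensity trend, and at 6 h 37 with a pseudocount of 64. Without the 1 h control arrays numbered 2, more passed at 1 h. That fit kept only those numbered 1, which lay apart from the other 1 h arrays on the second principal component. Without those numbered 1, fewer passed at 1 h. The closing section gives both counts. With only the 4 arrays of a time in the fit 0 passed at each time, and AT5G10830, AT3G03670, AT3G63360, AT4G20930 and AT5G61710 were not called after median centring.

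**Figure D3:**
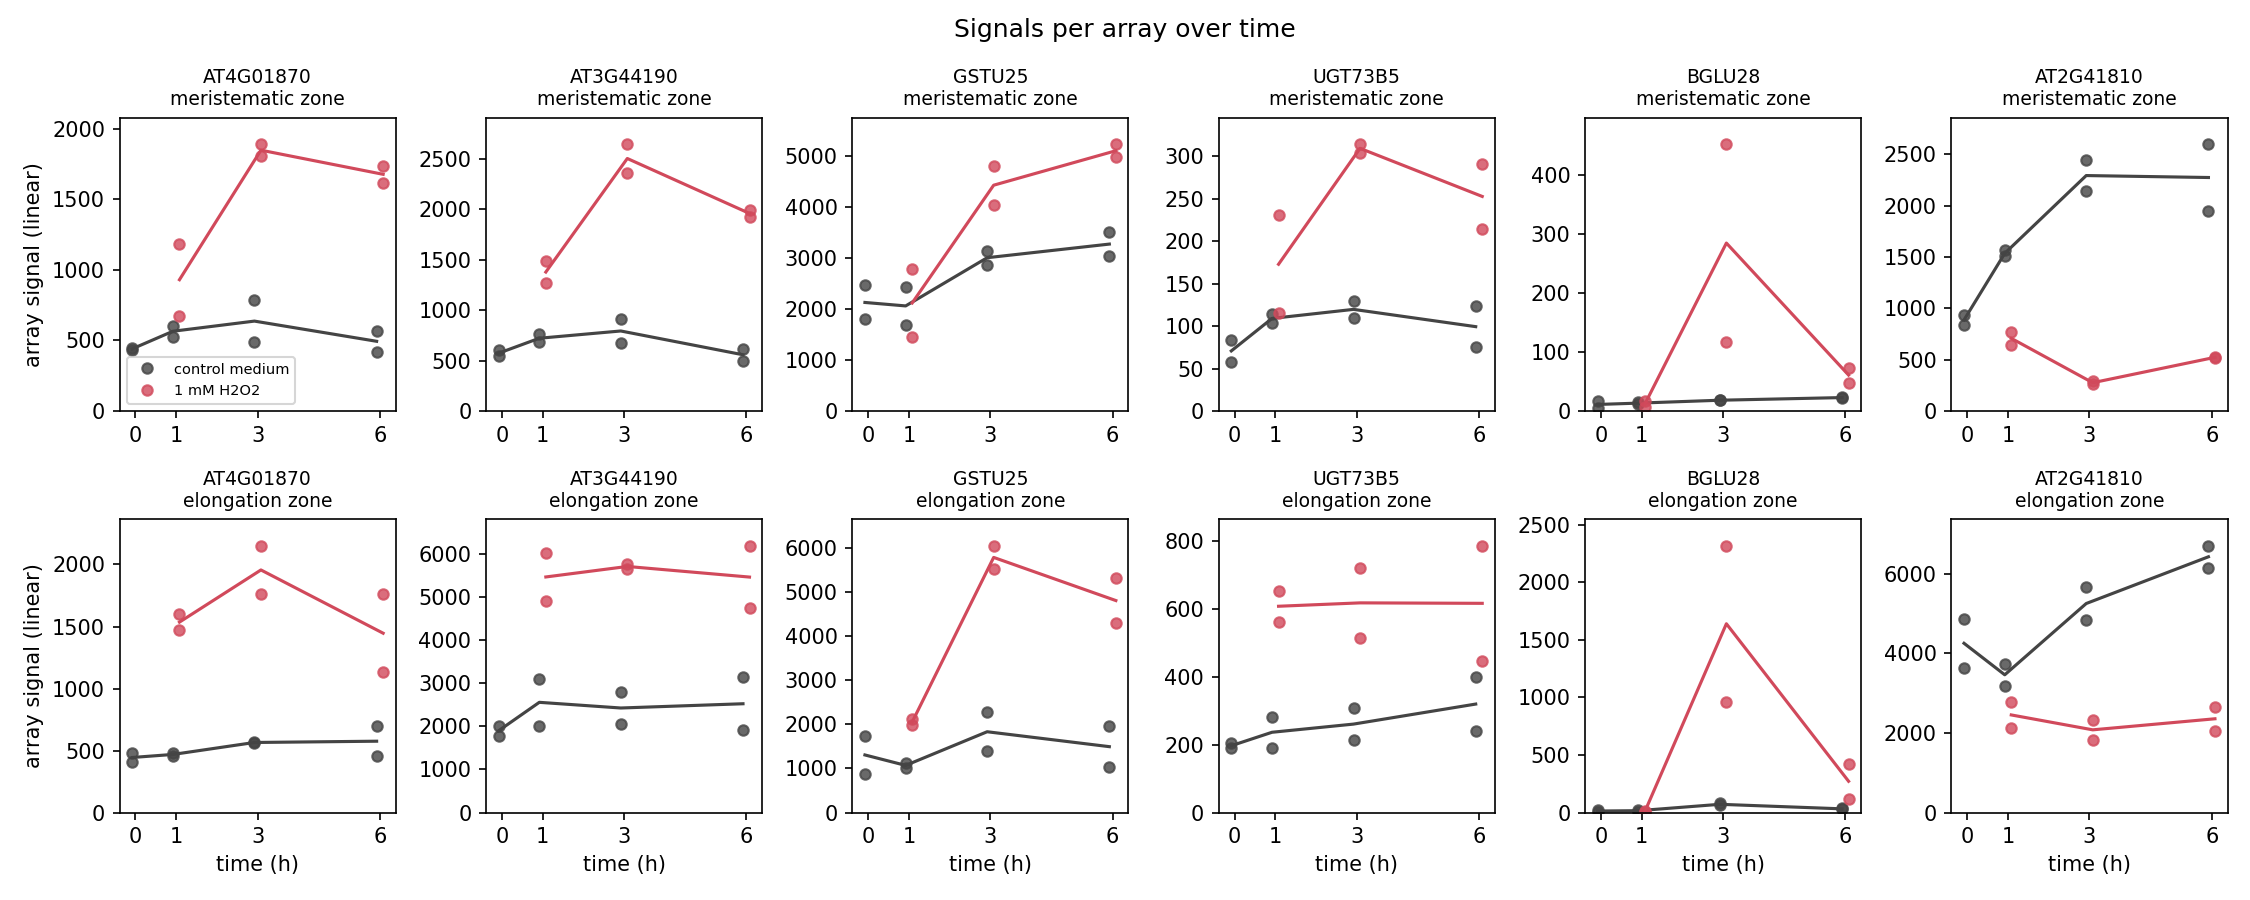
Linear array signal against time (h) for 6 genes in the meristematic (upper) and elongation (lower) zone, 1 point per array and lines through the means, control medium in grey and 1 mM H2O2 in red. AT2G41810 on control medium in the meristematic zone had a mean signal of 2292 at 3 h, against 275 on H2O2.

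The mean over 1, 3 and 6 h, added after the values were seen, used 6 arrays per medium and zone. Genes higher on H2O2 in both zones were AT4G01870 (1.32 ± 0.15 in the meristematic and 1.58 ± 0.15 in the elongation zone), AT3G26470 (1.60 ± 0.27 and 1.69 ± 0.27) and the neighbouring acyltransferase-type genes AT5G07860 (1.44 ± 0.25 and 1.54 ± 0.25) and AT5G07870 (1.21 ± 0.19 and 1.37 ± 0.19). AT5G64250 (0.99 ± 0.19 and 1.40 ± 0.19) rose too, as did the glucosyltransferases UGT73B5 (1.01 ± 0.18 and 1.14 ± 0.18) and UGT73B4 (0.85 ± 0.16 and 1.04 ± 0.16). AT2G41810 fell by 2.05 ± 0.11 in the meristematic zone and was 2.14-fold lower in the elongation zone (adjusted p = 1.4e-05). The pectin lyase-like gene AT2G43890 fell by 1.05 ± 0.19 and 1.07 ± 0.19.

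In the meristematic zone 59 probe sets passed for this mean (48 higher, 11 lower). AT4G14980 (-0.90 ± 0.16), AT5G51310 (-0.87 ± 0.18) and AT1G36060 (-0.76 ± 0.14) fell there. The elongation zone had 115 (97 higher, 18 lower), and 6 of 100 ways to split its arrays gave as many. With the position of each array on an axis between the zones of the 0 h controls as a covariate, 112 passed. Then 1 of 100 splits, the real one, gave as many, but that covariate was chosen after the first splits were seen. In the elongation zone 29.6 ± 0.964% of probe sets had a signal under 16 on H2O2 and 28 ± 0.933% on control medium (SD, n = 6 each, exact permutation p = 0.0463, adjusted p = 0.278). BGLU28 (2.03 ± 0.32), AT2G41380 (1.74 ± 0.23), AT5G14730 (1.68 ± 0.27), GSTU25 (1.45 ± 0.19) and GT72B1 (1.40 ± 0.18) rose there, and AT2G16660 (-1.02 ± 0.18) fell. The transcription factor WRKY6 rose by 0.62 ± 0.12 in the elongation zone (adjusted p = 0.0184), and its value in the meristematic zone was 0.28 ± 0.12 (adjusted p = 0.815). Averaged over both zones 212 passed, 174 higher and 38 lower. With the replicate number as a block, 111, 209 and 330 passed in the meristematic zone, in the elongation zone and over both zones.

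Of the probe sets higher in either zone, 34 were called in both, where independent lists of 48 and 97 would share 0.2. Of those lower, 3 were shared, where independent lists of 11 and 18 would share 0.0087. The zones had separate arrays and controls, but roots of 1 pool may have given both. Leaving out 1 array moved the meristematic count to 35 (control 1 h replicate 1), 36 (control 3 h replicate 1), 37 (H2O2 3 h replicate 2), 38 (control 6 h replicate 1) or 31 (H2O2 6 h replicate 2). It moved the elongation count to 377 (control 1 h replicate 2), 67 (H2O2 1 h replicate 2), 74 (control 3 h replicate 1), 75 (H2O2 3 h replicate 1), 63 (control 6 h replicate 1) or 71 (H2O2 6 h replicate 2), and the count over both zones to 139, 430 or 135 (meristematic control 1 h replicate 1, elongation control 1 h replicate 2, elongation control 6 h replicate 1). Without the 1 h control arrays numbered 2 the counts were higher, as the closing section gives, but only the outlying arrays numbered 1 were then left as 1 h controls. Without those numbered 1 the counts stayed within 1.5 times. With only the arrays compared in the fit the elongation count was 47.

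**Figure D4:**
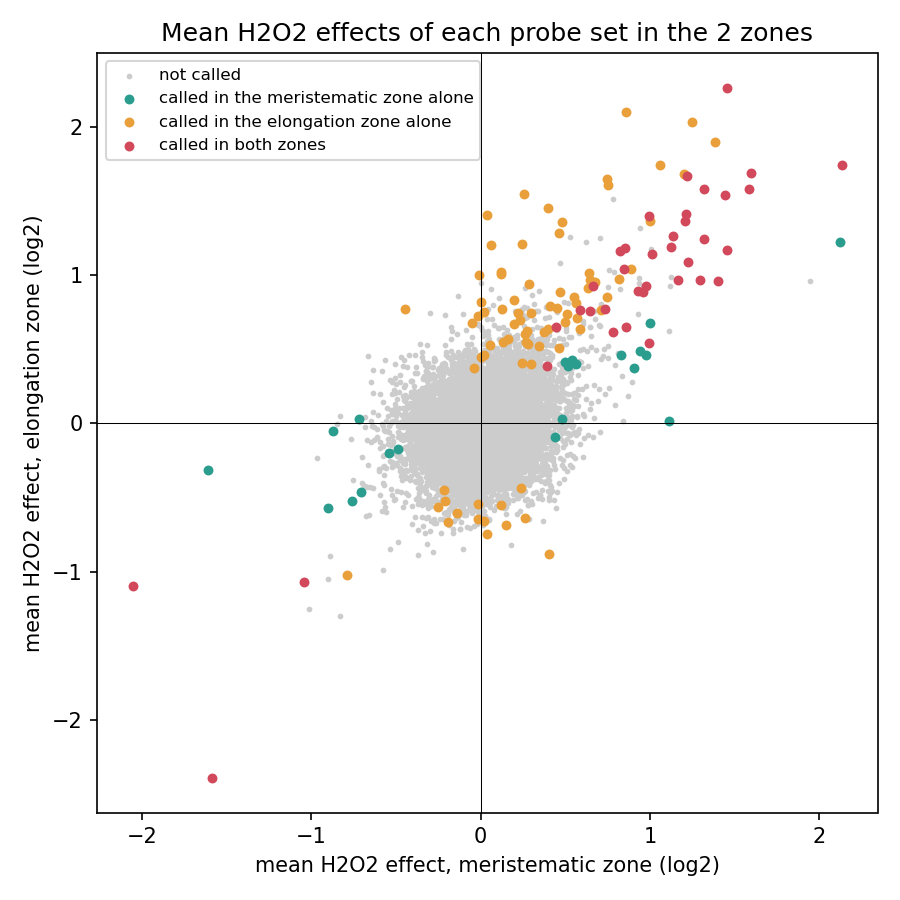
Mean H2O2 effect over 1, 3 and 6 h (log2 fold change) in the meristematic against the elongation zone, 1 point per probe set, coloured where the adjusted p was under 0.05. The 34 probe sets higher in both zones lie in the upper right.

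Among the fixed lists, glutathione transferases and detoxification genes stood out on H2O2. In the meristematic zone 12 of 13 members had a positive log2 fold change at 3 h and 9 at 6 h. No member passed there over all probe sets, and adjusted over the list alone 2 and 5 were higher. In the elongation zone 8 of 13 were positive at 3 h, with a median of 0.06, and 9 at 6 h, with a median of 0.24. Adjusted over the list alone, 3 were higher and 1 lower at 3 h, and 3 were higher at 6 h. Camera called the list at 3 h (adjusted p = 2.27e-04) and 6 h (adjusted p = 2.93e-04), and in the elongation zone at 3 h and 6 h (adjusted p = 0.00761 each). With an estimated correlation none of these 4 calls held (adjusted p = 0.0893, 0.0893, 0.197 and 0.197). Nor did any of them hold by fry (adjusted p = 0.0729, 0.0729, 0.405 and 0.169). For the mean effect in the meristematic zone the call held (adjusted p = 5.76e-07, and adjusted p = 0.0103 with an estimated correlation), with UGT73B4 and UGT73B5 as the 2 members called. For the elongation zone, GSTU25, UGT73B4 and UGT73B5 were the 3 called of 13 (camera adjusted p = 8.4e-04, and adjusted p = 0.077 with an estimated correlation). By fry the list passed for the mean effect in the meristematic (adjusted p = 0.00464) and the elongation zone (adjusted p = 0.0318). GSTU22 was called for the mean over both zones (0.69 ± 0.15, adjusted p = 0.0298). On the zone axis drawn from the 0 h control arrays, H2O2 arrays of 6 h lay 0.174 farther toward the elongation zone than control arrays. The exact permutation p was 0.0556, the smallest that 36 arrangements can give.

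The other 5 lists were not called in any of the 6 H2O2 contrasts. The smallest adjusted p was 0.134 for both antioxidant enzymes (meristematic zone, 6 h) and class III peroxidases (elongation zone, 1 h), and it was 0.199 for expansins and xyloglucan hydrolases, 0.199 for heat shock proteins and 0.668 for auxin genes. In these contrasts AT2G18980 was the only called member of those 5 lists. None of the 35 measured genes of the shorter lists passed by limma in these 6 contrasts. Coverage limits this: 5 of 35 antioxidant enzymes, 7 of 22 heat shock proteins and 9 of 29 auxin genes were measured. For expansins and xyloglucan hydrolases it was 13 of 32, for class III peroxidases 34 of 51, and for oxidative stress transcription factors 3 of 23. The response of the unmeasured members is not known here.

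The test of the difference between zones asked whether elongating cells respond unlike dividing cells. AT5G53320, named as a leucine-rich repeat receptor kinase family gene, was the 1 probe set that passed, at 6 h, with a difference of 1.84 ± 0.25 (adjusted p = 0.0118), at signals of at most 49.6 in the means of both media. That call was lost in 7 of the 8 fits that left out 1 of its arrays, all but the one without elongation H2O2 replicate 1, and also with a pseudocount of 1, with dim probe sets left out and with only the arrays compared in the fit. At 1 h and 3 h limma called 0, with 728 and 943 at an unadjusted p under 0.05. Both counts were below the share of 0.05 of 22746 probe sets that no effect would give. For the mean effect limma called 0, with 971 at an unadjusted p under 0.05, also below that share. It called 1 with a pseudocount of 1 or 64, with dim probe sets left out, without the 1 h arrays, or without elongation H2O2 1 h replicate 1, elongation H2O2 6 h replicate 2 or either meristematic control array at 6 h, and 2 with quantile normalisation, median centring or root pools as a block. GSTU25 had 1.45 ± 0.19 in the elongation and 0.39 ± 0.19 in the meristematic zone, a difference of 1.06 ± 0.27 that did not pass (adjusted p = 0.562). None of the 6 lists was called for a zone difference at 1, 3 or 6 h (smallest camera adjusted p = 0.748) or in the mean effect (0.254, for class III peroxidases).

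The change of the response from 1 h to 6 h passed for 1 probe set with no gene named here in the meristematic zone (2.28). Elongating cells had 3, AT5G53320 (3.12 ± 0.25, adjusted p = 2.23e-06), AT4G20930 (2.42 ± 0.37, adjusted p = 0.0325) and an unnamed probe set (-1.04). With dim probe sets left out 2 passed in the meristematic and 0 in the elongation zone, and with only the arrays compared in the fit 0 passed in both. Leaving out 1 array gave 5 in the meristematic zone without control 1 h replicate 1 and 0 without H2O2 6 h replicate 2. The elongation zone gave 10 or 30 without control 1 h replicate 1 or 2, and 1 without control 6 h replicate 1 or 2 or without H2O2 6 h replicate 1.

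Control roots were followed over time to see changes without H2O2. In the meristematic zone, AT2G41810 rose on control medium from 886 ± 65.4 at 0 h to 2292 ± 210 at 3 h (SD, n = 2 each; 1.35 ± 0.18, adjusted p = 0.0039), while on H2O2 its signal at 3 h was 275 ± 18.4. The peroxidase AT2G18980 rose by 1.53 ± 0.20 by 1 h and by 1.53 ± 0.20 by 3 h, and the pectin methylesterase gene AT3G10720 rose by 1.24 ± 0.18 by 6 h. BZIP61 was higher at 1 h (1.36 ± 0.14, adjusted p = 1.43e-04). In the elongation zone AT4G18280 rose by 3.08 ± 0.35 and AT2G23120, of the late embryogenesis abundant type, by 1.16 ± 0.19 at 1 h, and AT5G62340 fell by 1.86 ± 0.22 by 3 h. Of the 278 probe sets called at 1 h against 0 h there, 93.5% moved in the direction of the zone difference. With the position on a zone axis drawn from H2O2 arrays as a covariate, 2 were called. Leaving out 1 array moved the count to far lower or far higher values.

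Class III peroxidases were higher in the elongation zone at 6 h than at 0 h as a list, with 30 of 34 positive (camera adjusted p = 1.62e-09, and adjusted p = 0.00817 with an estimated correlation), although no member passed over all probe sets. On the zone axis drawn from H2O2 arrays, the 0 h elongation arrays lay 0.387 nearer the meristematic zone than later control arrays. The exact permutation p was 0.0357, the smallest that 28 arrangements can give, in a test chosen after the values were seen. The 0 h meristematic arrays (-1.262 and -1.244) also lay below later ones of their zone (-1.145 to -0.958). Camera also called the peroxidases there at 1 h and 3 h (adjusted p = 7.2e-04 and 0.00505) and in the meristematic zone at 6 h (adjusted p = 0.00146), but not with an estimated correlation (adjusted p = 0.084, 0.127 and 0.084). The same held in the elongation zone for glutathione transferases at 1, 3 and 6 h (adjusted p = 0.0404, 0.00254 and 0.0111, and adjusted p = 0.24, 0.084 and 0.157 with an estimated correlation) and for expansins and xyloglucan hydrolases at 3 and 6 h (adjusted p = 0.00505 and 0.0111, and adjusted p = 0.084 each with an estimated correlation). By fry the peroxidases passed in the elongation zone at 1 h and 6 h (adjusted p = 0.0198 and 0.00659), not at 3 h (adjusted p = 0.0819). In the meristematic zone they passed by fry at 6 h (adjusted p = 0.034). In the elongation zone glutathione transferases passed by fry at 3 h (adjusted p = 0.034), not at 1 h or 6 h (adjusted p = 0.0944 and 0.13). Expansins and xyloglucan hydrolases passed by fry there at 3 h and 6 h (adjusted p = 0.0198 and 0.034). The F test over time called 83 probe sets in the meristematic and 96 in the elongation zone. With the replicate number as a block it called 234 and 415. Leaving out 1 control array gave 45 (0 h replicate 2), 36 (1 h replicate 2) and 54 (3 h replicate 1) in the meristematic zone, and 43 (0 h replicate 1), 887 (1 h replicate 1) and 58 (6 h replicate 1) in the elongation zone. With only the control arrays of the zone in the fit, 0 and 1 passed.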

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

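All tests of explanations in this part were chosen after the results were seen. Each of these results stood out because the H2O2 response differed between zones or between times in a test of the difference itself. AT5G53320 differed between the zones at 6 h by 1.84 (log2, adjusted p = 0.0118) and changed from 1 h to 6 h in the elongation zone by 3.12 (adjusted p = 2.23e-06). AT4G20930 changed from 1 h to 6 h in the elongation zone by 2.42 (adjusted p = 0.0325), and an unnamed probe set by -1.04 (adjusted p = 0.0455). In the meristematic zone an unnamed probe set changed by 2.28 (adjusted p = 0.00267). The call of AT5G53320 between the zones was lost without any 1 of its 8 arrays except elongation H2O2 replicate 1 at 6 h.

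The control arrays numbered 1 at 1 h, 1 from each zone, lie apart from the other 1 h arrays. On an axis where the 3 and 6 h H2O2 arrays average 0 and the 1 h H2O2 arrays average 1, these 2 lie at 0.55 and 0.45, a mean of 0.5, among the 0 h arrays (0.41 to 0.55), while the lowest of the other 1 h arrays lies at 0.8 and the highest 3 or 6 h array at 0.39. A swap with another array of the series would need a partner at 0.8 or above among the 0, 3 and 6 h arrays, and the highest of these lies at 0.55, which argues against it. A wrong time label, 0 h among others, or other handling of 1 pool of roots may have given the 0.5, and a biological difference between root pools was not tested. These cannot be told apart, because both arrays carry the same number and no record of sampling was given. Replicate 1 also lay below replicate 2 on this axis in the 0, 3 and 6 h controls of both zones, such as 0.09 and 0.39 for meristematic 3 h. Among H2O2 groups it lay below at 3 h in both zones and at 6 h in the elongation zone. It was level in the meristematic zone at 1 h and 6 h, and above in the elongation zone at 1 h (1.02 and 0.98). A difference by replicate number was thus not limited to the 1 h controls.

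In the elongation zone of control roots 278 probe sets differed between 1 h and 0 h, against 4 at 3 h and 11 at 6 h. Of the 278, 93.5% moved in the direction of the difference between the zones, against 63.1% of all probe sets, so 0 h sections that hold more of the meristematic zone are a candidate explanation. The 0 h arrays lay at -0.387 relative to later control arrays on a zone axis drawn from H2O2 arrays. The exact permutation p of 0.0357 is the smallest that 28 arrangements can give. The elongation controls lay at 0.605 and 1.03 at 1 h, 0.699 and 0.892 at 3 h, and 0.724 and 0.88 at 6 h. Position alone therefore does not account for 278 calls at 1 h against 4 and 11 later. The 0 h meristematic arrays also lay lowest of their zone's controls (-1.262 and -1.244, against -1.145 to -0.958 later), and time after transfer cannot be told apart from a shift in section, since 0 h is 1 time point with 2 arrays per zone. With the position on that axis as a covariate 2 of the 278 stayed called, as their median change went from 1.06 (median SE 0.22) to 0.64 (0.23), and without the covariate the count was 8 without 0 h replicate 1, 47 without 1 h replicate 2 and 1746 without 1 h replicate 1.

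Other splits of the elongation zone arrays called more probe sets than the real one for the mean H2O2 effect, up to 1343 against 115. With the position on a zone axis drawn from the 0 h control arrays as a covariate, the highest other split called 25 and the real one 112. Where the sections were taken may thus account for those splits. That axis rests on the 0 h arrays, whose sections are in question above. The replicate number was not tested as a source of those splits. With that covariate 89.1% of the H2O2 calls (155 of 174) stayed, where a probe set called in both zones counted once for each. As far as that axis measures the mix of zones, this argues against a different mix as the source of most H2O2 calls. The H2O2 arrays lay 0.0716 farther along the axis than control arrays over all times (exact p = 0.166), and 0.174 farther at 6 h, where the exact p of 0.0556 is the smallest that 36 arrangements can give. Whether H2O2 arrays differ in position stays open.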

How the results depend on the processing

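The mean effects and the contrast of 1 h with 3 and 6 h, under every setting, and the settings that leave out 1 h arrays were chosen after seeing the data. Of 2964 values of named genes over all settings, 2609 kept direction and call, 355 kept direction but lost the call and 0 reversed. These genes were named because they were called with large changes in the main fit. Their calls could only stay or be lost, and reversals were unlikely from the start. Signal over background limits dim genes: a filter at signal 32.7 kept 13647 probe sets and left out 9099. The cause of the moved counts below was not tested, except that fewer arrays in a fit leave fewer degrees of freedom. Counts not given here stayed within 1.5 times.

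Pseudocount 1 gave zone differences of 1 at 3 h and 0 at 6 h, changes from 1 h to 6 h of 3 (meristematic) and 6 (elongation), and 1 for the zone difference of the mean effect. Pseudocount 64 gave 11 and 37 for the elongation zone at 1 h and 6 h, 6 for its change and 1 for the mean difference. That difference was 2 with quantile normalisation, 2 with median centring and 1 without the 1 h arrays. Without dim probe sets, zone differences were 1 (3 h) and 0 (6 h), changes 2 and 0, and the mean difference 1. With no intensity trend, 2 passed in the meristematic zone at 3 h, 3 in the elongation zone at 1 h and 54 over time in the meristematic zone. With only the arrays compared, counts were 1 and 9 (meristematic, 3 h and 6 h), 0, 0 and 0 (elongation), 0 (zone difference, 6 h), 0 and 0 (changes), 47 (mean, elongation) and 0 and 1 (time). A log2 fold change of at least 1 left 5404 for the zones, 24, 43 and 38 for the mean effects (meristematic, elongation, both) and 308 for 1 h against 3 and 6 h. Against the 0 h control, counts were 48, 127 and 366 (meristematic) and 301, 631 and 1689 (elongation).

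The labels link arrays of different groups by replicate number alone and do not say whether a number marks 1 batch or 1 root pool. On the second principal component replicate 1 lay above replicate 2 in every group, so the number went with a difference across the series. Differences between replicates 1 and 2 correlated from -0.02 to 0.35 between H2O2 and control, from 0.06 to 0.44 between the zones (7 of 7 above 0), and from -0.11 to 0.44 over all 91 pairs of groups (83 above 0). The number as a block gave 6, 37 and 115 (meristematic), 38, 67 and 54 (elongation), 3 (change, meristematic), 111, 209 and 330 (mean effects) and 234 and 415 (time). Root pools as a random block (correlation 0.158) gave 1 (zone difference, 3 h), 2 (change, meristematic) and 2 (mean difference). Of the 1 h control arrays, those numbered 1 lay among the 0 h arrays on the 1 h axis. Leaving out those numbered 2 kept only these as 1 h controls. Without the 1 h control arrays numbered 1, 1 passed in the elongation zone at 1 h and 7 and 11 for the changes. Without those numbered 2, counts were 35 and 273 (1 h), 1 (zone difference, 1 h), 2 and 50 (changes) and 97, 394 and 606 (mean effects).

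With 1 array left out, where the lone array is taken to vary like the other groups, counts ranged from 12845 to 13265 (zones), 36 to 97 and 43 to 887 (time), 0 to 2, 1 to 9 and 2 to 35 (meristematic), 0 to 207, 1 to 17 and 2 to 18 (elongation), 0 to 1, 0 to 2 and 0 to 1 (zone differences), 0 to 5 and 1 to 30 (changes), 31 to 71, 63 to 377 and 135 to 430 (mean effects), 0 to 1 (mean difference), 723 to 1309 (1 h against 3 and 6 h) and 3 to 6 of the list calls, 4 with all arrays.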

Other observations

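The comparison of 1 h with 3 and 6 h among H2O2 arrays of both zones was chosen after seeing the data. GAT1_2.1, a glutamine amidotransferase-like gene, was higher at 1 h by 4.98 ± 0.38 (adjusted p = 1.64e-07), with a signal of 1002 ± 773 (SD, n = 4) at 1 h and a mean under 16 (n = 8) later. Its other probe set gave 0.68 ± 0.22 and was not called (adjusted p = 0.0783). AT3G15450 (3.51 ± 0.57), AT1G80380 (3.28 ± 0.27) and AT5G24490 (3.04 ± 0.37) were higher as well. IVD (1.96 ± 0.18), MCCA (2.40 ± 0.23) and MCCB (0.42 ± 0.12), picked after their values were seen, code for enzymes of leucine breakdown and were also higher at 1 h. That pathway was not tested as a list. EXO was higher too (2.22 ± 0.22). Lower at 1 h were BGLU28 (-3.47 ± 0.33), MSRB5 (-1.87 ± 0.19), UGT78D2 (-1.96 ± 0.26), UGT84A1 (-1.80 ± 0.25) and CHIL (-1.60 ± 0.22). In all 1331 probe sets passed by limma, 678 higher and 653 lower, and 498 higher and 900 lower after median centring. Leaving out 1 array lowered the count to 723, 781 or 736 (meristematic H2O2 1 h replicate 1 or 2, elongation H2O2 1 h replicate 1).

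The control arrays of 1 h differed in these genes, and those numbered 1 lay where 0 h arrays lie on the 1 h axis (0.55 and 0.45, against 0.41 to 0.55). The elongation zone signal of GAT1_2.1 was 207 on control replicate 1 and 1140 on replicate 2, with a mean of 1670 on H2O2, and that of MCCA was 245, 721 and 929. In the meristematic zone GAT1_2.1 gave 90.4, 267 and 333, and IVD gave 445, 771 and 638.

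Families of genes that share a symbol were tested after the data were seen. In control roots 17 of 23 TBL genes, which act in acetylation of wall polysaccharides, were higher in the elongation zone and 2 lower (camera adjusted p = 5.21e-04, and adjusted p = 0.0444 with an estimated correlation). Of 11 PRA genes of membrane traffic 7 were higher and 0 lower (camera adjusted p = 0.00811, and adjusted p = 0.244 with an estimated correlation). All 6 measured genes that share the symbol NRPB, subunits of RNA polymerase II, were lower (camera adjusted p = 0.0223, and adjusted p = 0.598 with an estimated correlation). Some of them also carry NRPD and NRPE symbols, so they are not particular to that polymerase.

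The arrays were also split in 100 ways, the real one included, with zones exchanged within each time, or media within each zone and time. For the zone comparison 1 split was as large, the real one (13259 probe sets, highest other split 10676), so chance is excluded at 0.05. The mean H2O2 effect in the meristematic zone also had 1 split as large (59, highest other 48). That contrast was added after the values were seen, so 1 of 100 counts against chance without excluding it. Over both zones 212 passed and 2 splits gave as many, the highest other 555. This contrast was also added late, and media were exchanged separately in each zone although roots of 1 pool may have given both. The splits therefore do not exclude chance over both zones. For the elongation zone chance cannot be excluded in the fit without a covariate: 115 passed, 6 splits gave as many, and the highest other gave 1343, several times the real count, which points to a structure among the arrays. That split put control replicate 1 at 1 h and 3 h, H2O2 replicate 1 at 1 h, H2O2 replicate 2 at 3 h and both control arrays at 6 h on 1 side. With the position on the zone axis of the 0 h control arrays as a covariate, the real split called 112, the highest other 25, and 1 of 100 gave as many. That covariate was chosen after the splits without it were seen, so this fit does not exclude chance. For the zone difference in the mean effect 0 passed by limma, all 100 splits gave as many and the highest other gave 434. An unadjusted p under 0.05 was found for 971, fewer than the share of 0.05 of 22746 that no effect would give. For 1 h against 3 and 6 h, with times exchanged within each zone, 1 split gave 1331 and the highest other 154, but that contrast was picked because these arrays lay apart, so this says nothing about chance.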
